A study of Homo sapiens with 6 samples.

How the data were processed

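The series holds 6 RNA-seq libraries of MIA PaCa-2, an established human pancreatic carcinoma cell line. Per the labels, cells were grown for 5 days on polyacrylamide hydrogels of 2.55 kPa (soft, n = 3) or 40.40 kPa (stiff, n = 3). Samples were grouped by the stiffness in the labels and keep the replicate numbers of their titles. All 6 carry 1 batch label. Per the labels' protocols, libraries were made from total RNA with an Illumina TruSeq RNA kit. Whether strand was kept is not given in the sources used here, so overlapping and antisense genes cannot be told apart by their reads.

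The authors deposited 1 table with 62703 gene rows, of which 41737 carry a symbol. It holds estimated counts per gene and library, which per the file headers are counts, and of whose nonzero values 33.2% have decimals. It also holds TPM per library and the authors' mean TPM per group, both as deposited by the authors. The authors' fold (a ratio of stiff over soft), their log2 fold change, and their p-value and adjusted p-value are deposited beside them, per the file headers. The submitters' processing notes name Bowtie 1.0.0. The counter, genome build, annotation and statistical test are not given in the sources used here. The authors' mean TPM was not used here, and their comparison columns were used only to set their calls beside those computed here.

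Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Normalisation was by TMM, genes were kept by filterByExpr with its default settings, and the quasi-likelihood test was robust, with stiffness as the only term. This left 16328 genes, and 29830 rows had no count in any library. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Adjusted p-values for genes come from this edgeR test unless another tool is named. CPM values are normalised by the TMM-scaled library sizes and are given as mean ± SD over 3 libraries. The standard error of a log2 fold change is its size over the square root of the quasi-likelihood F. Positions are those of GENCODE 29 on GRCh38, matched by Ensembl identifier for 58279 rows.

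Before the data were examined, 25 gene lists were fixed. They covered glycolysis and lactate export, HIF targets, autophagy, lysosome, FOXO factors and targets, YAP/TAZ targets, actomyosin and SRF targets, integrins and focal adhesion, and extracellular matrix. Others were mesenchymal and epithelial markers, proliferation, nuclear and mitochondrially encoded respiratory genes, cholesterol synthesis, ATF4 and the unfolded protein response, interferon, NF-kB and cytokines, and heat shock with immediate early genes. The rest were protein acetylation and lactylation enzymes, replication-dependent histones, and markers of fibroblasts, leukocytes, endothelium and acinar or islet cells. All 556 list entries matched a row. Lists with at least 5 tested genes were tested with limma 3.58.1 camera, two-sided, at a preset inter-gene correlation of 0.01, with adjustment over the 22 lists that qualified. KEGG pathways and GO biological processes that the table assigns to genes were tested with two-sided Fisher's exact tests on terms of 10 to 500 tested genes. Risen and fallen genes were tested apart, against all genes tested.

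Named genes followed a rule fixed before the data were examined. It took 9 genes of prior interest (LDHA, LDHB, FOXO3, SQSTM1, MAP1LC3B, BECN1, CCN1, CCN2 and ANKRD1). It added the 8 largest rises and the 8 largest falls among called protein-coding genes with a symbol, a mean of at least 5 CPM and no overlap between the groups. It also took the 3 members of each list with the lowest adjusted p among those called, or the member with the lowest p where none was called. Other genes were chosen after their values were seen. In the results these are FOXO1 and FOXO4, and the members named as moving against their list (PFKM, CCNE2, CDC6, PSMB9, ATF4, PHGDH, PSAT1, ASNS and SLC7A5).

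Total estimated counts per library lay between 18490082 and 24555560. The test was run on simulated counts with 200 of 16094 genes changed, drawn with the means, library sizes and dispersion of these data. It recovered 58% of genes changed 1.25-fold, 88% at 1.5-fold, 86% at 2-fold and 98% at 3-fold, and 6 of its 171 calls (3.5%) were false. Far more genes, 6544, were called in the data, which alters the adjustment of p-values. The simulated genes also followed the dispersion trend, with no spread of their own around it. These rates therefore need not hold for the data. Chi-square values per gene between libraries of the same group were 1.86 to 4.118, so no pair agreed within sampling noise and all 6 libraries were kept.

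Alternatives tried were RLE size factors and library size alone, no filter and a filter of 1 CPM in 3 libraries, each replicate left out, and the replicate number as a block. Others were DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, and limma on log2(TPM + pseudocount) with pseudocounts of 1, 0.1 and 0.01 at a minimum of 1 TPM and with no filter. Lists were also tested with an estimated correlation and with fry. After seeing the data, a test against a 1.2-fold change, a spread set to a coefficient of variation of 10%, removal of each library's GC and length trends, removal of mitochondrially encoded genes and a background of annotated genes were added.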

Results

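RNA was sequenced from MIA PaCa-2 cells, a human pancreatic ductal adenocarcinoma line, after 5 days on polyacrylamide hydrogels of 2.55 kPa (soft) or 40.40 kPa (stiff). Each stiffness had 3 libraries. Total estimated counts were 19173644, 18490082 and 24555560 in the soft libraries and 21641909, 20750678 and 23733751 in the stiff libraries. Genes with a count numbered 24190 to 25162 in soft and 24855 to 25696 in stiff libraries. Mitochondrially encoded genes took 8.03%, 8.30% and 7.80% of counts in the soft and 6.73%, 6.48% and 6.48% in the stiff libraries. The first principal component of log2 CPM held 45.0% of the variance and separated the groups. Replicates lay close together, with a biological coefficient of variation of 3.66%. Nothing in the labels shows that the replicates were separate cultures, so p-values measure only the spread between these samples, part or all of which is possibly technical.

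The contrast of stiff against soft asks which transcripts change with the stiffness of the matrix. The series title puts LDHA, autophagy and FOXO3 at its centre. On the stiff gel, genes of glycolysis and targets of the hypoxia-inducible factors (HIF) rose. Most listed genes of cholesterol synthesis (19 of 22) and proliferation (23 of 29) fell. Most listed respiratory genes fell too, but the calls of both respiratory lists were lost with an estimated correlation (adjusted p = 0.178 for each by camera). FOXO3 rose slightly, and autophagy genes went both ways. Of 16328 genes tested, 6544 changed (40.1%), 3203 up and 3341 down, by edgeR's quasi-likelihood test. Most changes were small. The median absolute log2 fold change of the changed genes was 0.27, and 84.8% of them changed by less than 1.5-fold. At least 2-fold changes were found in 324 genes, 245 up and 79 down. This count was 210 with at least 1 CPM in 3 libraries and 107, 216 and 215 on the TPM scale with pseudocounts of 1, 0.1 and 0.01 (97 with no filter). The groups did not overlap in 49.1% of all tested genes, where chance gives 10%. In limma fits on the authors' TPM, 3509 genes changed and 71.6% of them rose, against 49.0% of the calls on counts. The TPM values were not scaled further between libraries. The median log2 fold change of all genes tested was 0.068 there, against -0.0019 on counts. Such a shift favours calls of rises and works against calls of small falls. Tested against a 1.2-fold change, 1383 genes passed, and 17 of the named genes lost their call, among them VIM, ATP5F1B, MT-ND5, DNAJB1, DUSP1 and HSPA8. The same 17 lost it with the coefficient of variation set to 10%, among them also SQSTM1 (adjusted p = 0.213 by edgeR), PIK3R4 (0.0581), NPC1, AARS1, UQCRC2 and LDHB. Both settings turn mainly on the size of a change. The authors' deposited table marks 5513 genes as significant, and 5492 of these were called here in the same direction.

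LDHA, which encodes the A subunit of lactate dehydrogenase, was at 2456 ± 22.3 CPM on soft and 4271 ± 11.9 CPM on stiff gels (SD, n = 3). Its log2 fold change was 0.80 ± 0.01 (SE), with an adjusted p of 5.06e-27 by edgeR, and it was higher in 3 of 3 stiff libraries. LDHA (ENSG00000134333) lies on chromosome 11 at 18394388 to 18408425 on the plus strand of GRCh38. The B subunit gene LDHB had a log2 fold change of -0.10 ± 0.02 (adjusted p = 0.000627 by edgeR), a call that was lost on the TPM scale (log2 fold change -0.0063). FOXO3, a forkhead transcription factor gene (ENSG00000118689, chromosome 6, 108559835 to 108684774, plus strand), was at 114 ± 2.95 CPM on soft and 130.0 ± 2.62 CPM on stiff gels. Its log2 fold change was 0.19 ± 0.03 (adjusted p = 9.64e-06 by edgeR). FOXO3 did not pass a test against a 1.2-fold change (adjusted p = 1) or a test with the coefficient of variation set to 10% (adjusted p = 0.318). In the authors' deposited table the log2 fold changes are 0.80 for LDHA and 0.19 for FOXO3.

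**Figure D1:**
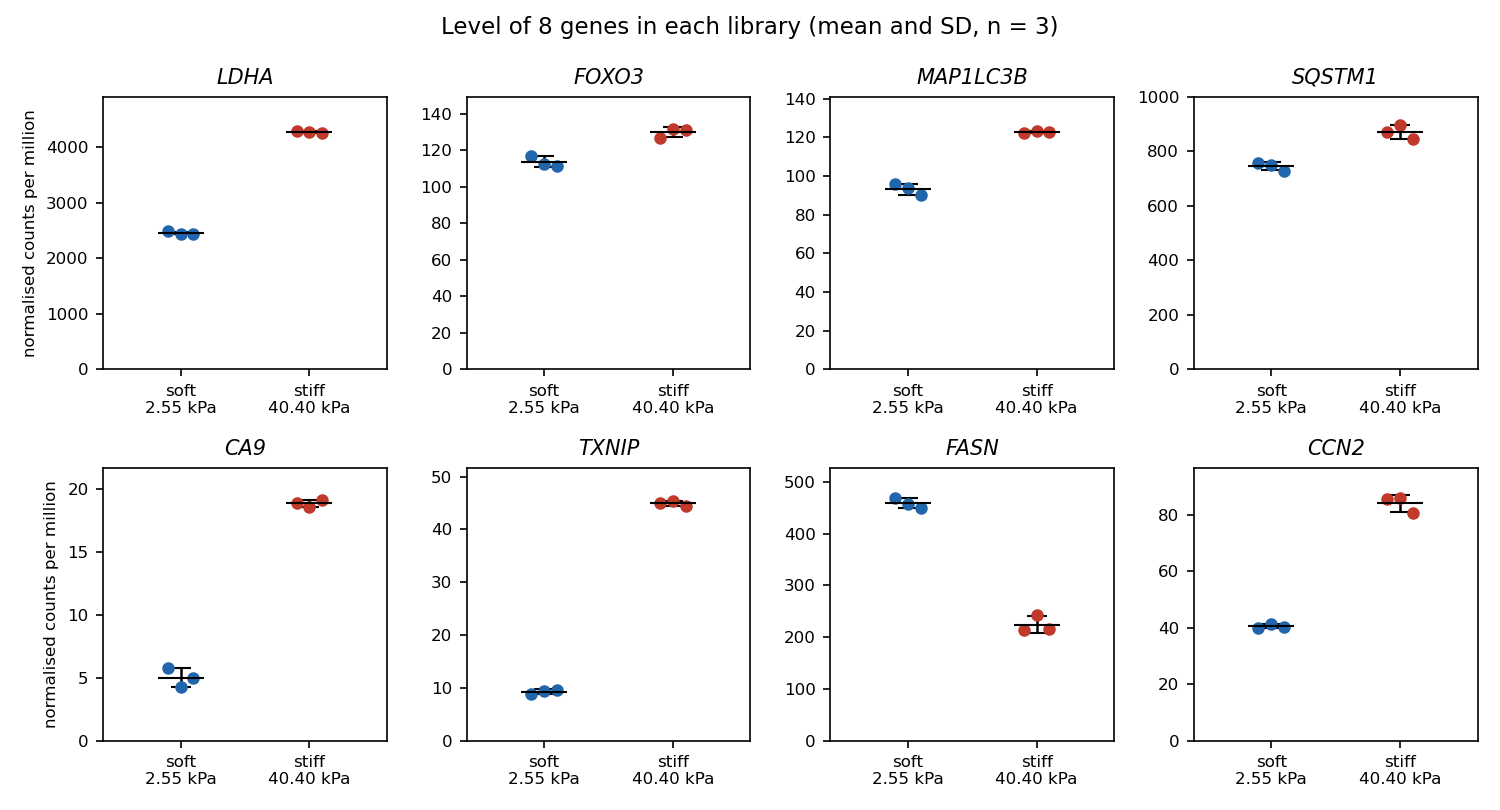
Normalised CPM (vertical axes, from 0) of 8 genes in the soft (blue) and stiff (red) libraries. Points are libraries, and black bars are the mean and SD of 3 libraries. LDHA was near 2456 CPM in the soft and 4271 CPM in the stiff libraries, while FOXO3 moved from 114 to 130.0 CPM and FASN fell from 458 to 224 CPM.

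All 23 HIF targets outside glycolysis rose, with a median log2 fold change of 1.04 (camera adjusted p = 7.82e-114). P4HA1, a collagen prolyl hydroxylase subunit, rose by 1.40 ± 0.02. BNIP3, a mitophagy receptor, rose by 1.29 ± 0.03, and the histone demethylase gene KDM3A rose by 1.36 ± 0.03. Of 23 genes of glycolysis and lactate export, 21 rose and 2 fell (PFKM and LDHB), with a median of 0.69 (camera adjusted p = 9.89e-80). PGK1 rose from 932 ± 5.3 to 2045 ± 12.2 CPM and GPI from 841 ± 18.1 to 1901 ± 42.1 CPM. The glucose transporter gene SLC2A1 rose from 42.6 ± 0.63 to 113 ± 2.93 CPM. Both list calls held with an estimated correlation (adjusted p = 0.000336 and 0.00608). LDHA and PGK1 have processed copies, but the copies' counts were at most 0.0605% and 0.0381% of the gene's own.

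The 8 largest rises that met the rule were HMOX1, TXNIP, CP, NDRG1, CA9, OSGIN1, AK4 and SLC2A1. HMOX1, which encodes heme oxygenase 1, rose from 30.5 ± 2.08 to 149 ± 2.62 CPM (log2 fold change 2.30 ± 0.04). TXNIP, an inhibitor of thioredoxin, rose from 9.23 ± 0.457 to 44.9 ± 0.465 CPM. The ceruloplasmin gene CP rose by 2.09 ± 0.08, NDRG1 by 1.92 ± 0.05 and the carbonic anhydrase gene CA9 by 1.91 ± 0.10. OSGIN1 rose by 1.68 ± 0.13. AK4 rose by 1.48 ± 0.03, and its processed copies held 5.59% of its counts in soft libraries, so how reads were split between them is uncertain. Among the 8 largest falls were ERBB3, MUC5AC, LAT2, FASN, STARD8, AGAP2 and RAB3B. FASN, the fatty acid synthase gene, fell from 458 ± 9.43 to 224 ± 16.7 CPM (log2 fold change -1.03 ± 0.05). The gel-forming mucin gene MUC5AC fell from 7.36 ± 0.712 to 3.58 ± 0.633 CPM. The receptor gene ERBB3 fell from 11.8 ± 0.821 to 5.18 ± 0.778 CPM, but on the TPM scale its log2 fold change shrank from -1.19 to -0.42, -0.55 and -0.56 at pseudocounts of 1, 0.1 and 0.01, and its call was lost (adjusted p = 0.454 by limma at a pseudocount of 1). LAT2, STARD8, AGAP2 and RAB3B had log2 fold changes of -1.04, -0.95, -0.93 and -0.92. MUC5AC, AGAP2 and RAB3B lost their calls in the TPM fit with no filter.

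Of 42 autophagy genes, 11 rose, 7 fell and 24 did not pass, with a median log2 fold change of 0.05. The list as a whole did not differ from other genes (camera adjusted p = 0.379). MAP1LC3B, the gene of the autophagosome protein LC3B, rose from 93.3 ± 2.85 to 123 ± 0.45 CPM. The cargo receptor gene SQSTM1 rose by 0.23 ± 0.02, and PIK3R4, a subunit of the class III PI3-kinase complex, fell by 0.32 on the log2 scale. BECN1 had a log2 fold change of -0.14 ± 0.04 (adjusted p = 0.0137 by edgeR). Its call was lost without soft replicate 2 (adjusted p = 0.0599) or soft replicate 3 (adjusted p = 0.0593), with DESeq2 (adjusted p = 0.0801) and on the TPM scale (adjusted p = 0.289 by limma). SQSTM1 and PIK3R4 did not pass the test against a 1.2-fold change. Of 32 lysosome genes, 10 rose, 8 fell and 14 did not pass (camera adjusted p = 0.379). The lysosomal genes PSAP and CTSD rose by 0.38 ± 0.02 and 0.50 ± 0.03. The cholesterol exporter gene NPC1 had a log2 fold change of -0.21 ± 0.04, a call that was lost on the TPM scale (log2 fold change -0.0095). Both lists passed in the TPM fit with no filter (adjusted p = 0.0136 and 0.00525) and by fry.

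Of 27 FOXO factors and targets, 13 rose, 5 fell and 9 did not pass, with a median of 0.15 (camera adjusted p = 0.000104, and adjusted p = 0.0316 with an estimated correlation). TXNIP and CITED2 (0.62 ± 0.03) were the risen members with the lowest adjusted p. ERBB3, a gene that FOXO factors are known to induce, fell on counts but did not pass on the TPM scale. FOXO1 and FOXO4, chosen after their values were seen, had log2 fold changes of 0.05 ± 0.07 and -0.11 ± 0.10 and did not pass. Of 16 genes listed for protein acetylation and lactylation, 6 rose, 5 fell and 5 did not pass (camera adjusted p = 0.970). The list covers enzymes that add or remove acetyl or lactyl groups on proteins, except the acetyl-CoA synthetase gene ACSS2. ACSS2 fell by 0.62 on the log2 scale, and AARS1, an alanyl-tRNA synthetase with reported lactyltransferase activity, fell by 0.27. The acetyltransferase gene CREBBP rose by 0.34 ± 0.03. AARS1 lost its call in the test against a 1.2-fold change and in the TPM fit with no filter.

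**Figure D2:**
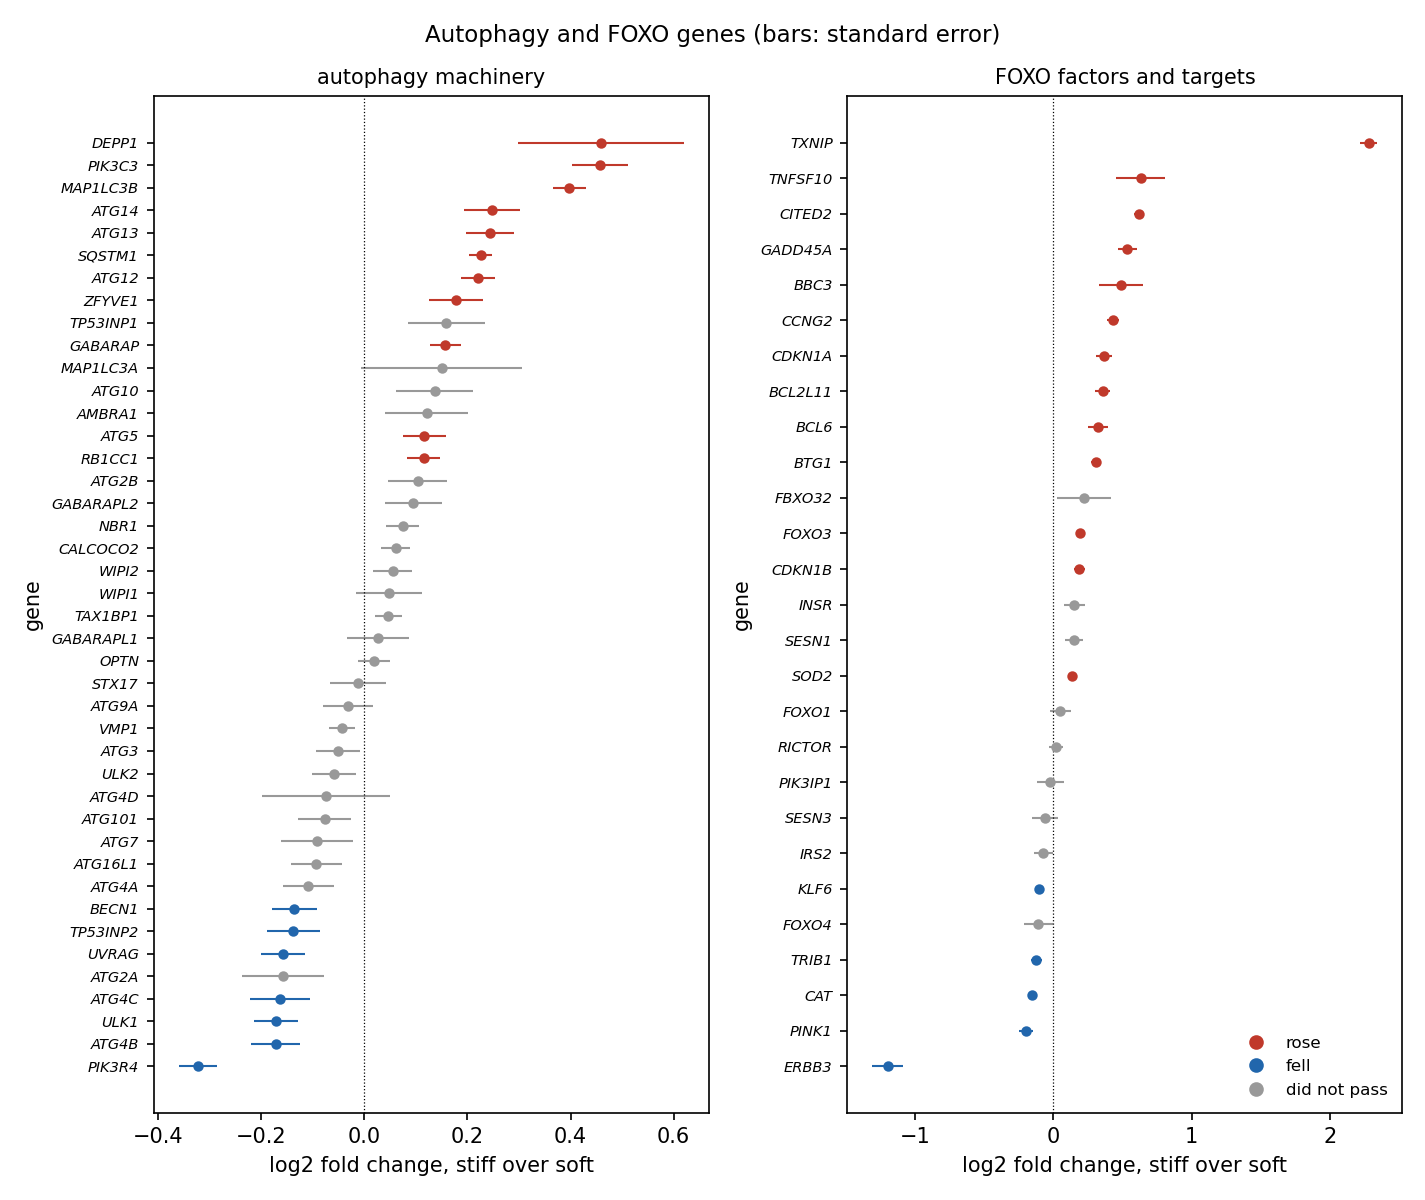
Log2 fold change of stiff over soft (horizontal axes) for each tested gene of the autophagy list (left, 42 genes) and of the FOXO list (right, 27 genes), with standard errors as bars. Red genes rose, blue genes fell and grey genes did not pass. In the autophagy list 11 rose and 7 fell, and in the FOXO list TXNIP stands at 2.28 and ERBB3 at -1.19.

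Genes tied to mechanical sensing went both ways. Of 25 YAP/TAZ targets, 5 rose, 12 fell and 8 did not pass (camera adjusted p = 0.533). CCN2 rose from 40.5 ± 0.679 to 84.0 ± 2.99 CPM, IGFBP3 rose from 10.3 ± 0.291 to 24.4 ± 2.25 CPM and CCN1 by 0.18 ± 0.02. The receptor tyrosine kinase gene AXL fell by 0.44 on the log2 scale. ANKRD1 was at 10.5 ± 0.558 and 10.1 ± 1.45 CPM (log2 fold change -0.05 ± 0.10, adjusted p = 0.729 by edgeR), and its sign turned on the TPM scale and without stiff replicate 2 (0.04). CCN1 did not pass the test against a 1.2-fold change. In the integrin and focal adhesion list 4 rose, 10 fell and 14 of 28 did not pass (camera adjusted p = 0.00664), and ITGA3 fell by 0.62, ITGA5 by 0.40 and ITGA6 by 0.34. ITGA5 lost its call in the TPM fit with no filter (adjusted p = 0.118 by limma). In the actomyosin and SRF list 4 rose, 10 fell and 12 of 26 did not pass (camera adjusted p = 0.0218), and TAGLN2 fell by 0.52 and LMNA by 0.40. In the extracellular matrix list 12 rose, 6 fell and 19 of 37 did not pass (camera adjusted p = 0.00661). There the collagen-modifying genes PLOD2 (0.62 ± 0.02) and P4HB (0.56 ± 0.02) rose, and the protease gene PLAU fell from 279 ± 2.66 to 157 ± 4.7 CPM. These 3 calls were lost with an estimated correlation (adjusted p = 0.178 for integrins, 0.368 for actomyosin and 0.178 for matrix). They were also lost on the TPM scale (adjusted p = 0.180, 0.199 and 0.199), though the matrix call was kept in the TPM fit with no filter (adjusted p = 0.0350). The actomyosin call was also lost without stiff replicate 1 (adjusted p = 0.0526).

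Of 22 cholesterol synthesis genes, 19 fell and none rose, with a median of -0.44 (camera adjusted p = 2.39e-24, and adjusted p = 0.00368 with an estimated correlation). FDFT1, which encodes squalene synthase, fell from 184 ± 5.26 to 110 ± 2.09 CPM. MSMO1 fell by 0.69 on the log2 scale. Of 29 proliferation genes, 23 fell and 2 rose, CCNE2 and CDC6 (median -0.34, camera adjusted p = 2.83e-13, and adjusted p = 0.0150 with an estimated correlation). TOP2A fell from 665 ± 20.7 to 494 ± 6.85 CPM, and BUB1 and AURKA each fell by 0.48. Of 32 nuclear genes of oxidative phosphorylation, 27 fell and none rose (median -0.17, camera adjusted p = 4.22e-07). SDHB fell by 0.42, ATP5F1B by 0.21 and UQCRC2 by 0.24, and the UQCRC2 call was lost on the TPM scale (adjusted p = 0.0514). Of 13 mitochondrially encoded mRNAs, 9 fell and none rose (median -0.45, camera adjusted p = 3.27e-09). MT-CO1 fell from 18197 ± 110 to 12560 ± 216 CPM, MT-ND2 by 0.45 and MT-ND5 by 0.22. Neither respiratory list call held with an estimated correlation (adjusted p = 0.178 for each).

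The list of ATF4 targets and the unfolded protein response had 17 risen, 5 fallen and 2 other genes (median 0.43, camera adjusted p = 9.11e-16, and adjusted p = 0.00881 with an estimated correlation). Its members moved apart. The endoplasmic reticulum chaperone genes HSP90B1 (0.86 ± 0.02) and HSPA5 (0.82 ± 0.02) and the stress gene HERPUD1 (1.29 ± 0.04) rose. ATF4 itself, the serine synthesis genes PHGDH and PSAT1, the asparagine synthetase gene ASNS and the transporter gene SLC7A5 fell. Of 25 interferon response genes, 15 rose and 1, PSMB9, fell (median 0.40, camera adjusted p = 2.52e-07, and adjusted p = 0.0206 with an estimated correlation). IFI6 rose by 1.10 ± 0.07, IFIT3 by 0.60 ± 0.05 and IFIT1 by 0.52 ± 0.03. Of 9 replication-dependent histone genes, 6 rose (median 0.62, camera adjusted p = 0.00505), a call that was lost with an estimated correlation (adjusted p = 0.0974). H2AC6 rose by 1.13 ± 0.13, H2BC5 by 0.70 ± 0.09 and H1-2 by 0.62 ± 0.11, and reads from such near-identical genes are uncertain.

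Other lists did not pass. Of 21 heat shock and immediate early genes, 3 rose and 11 fell (camera adjusted p = 0.0572), DNAJB1 by 0.27 and DUSP1 by 0.31, while HSPA8 rose by 0.11 ± 0.02. This list passed without soft replicate 1 (adjusted p = 0.0466), without soft replicate 3 (adjusted p = 0.0213) and without stiff replicate 3 (adjusted p = 0.0487). Of 18 NF-kB and cytokine genes, 5 rose and 8 fell (camera adjusted p = 0.379), with CXCL8 at 0.72 ± 0.05, CCL2 at -0.38 ± 0.02 and TNFAIP2 at -0.45 ± 0.02. Of 12 mesenchymal markers, 3 rose and 1 fell (camera adjusted p = 0.919), with VIM at 0.09 ± 0.02. ZEB2 was at 0.14 ± 0.05, a call that was lost without soft replicate 1 (adjusted p = 0.0975), soft replicate 2 (adjusted p = 0.137) or stiff replicate 3 (adjusted p = 0.114) and with DESeq2 (adjusted p = 0.107). The ZEB2 call was also lost with GC and length trends removed (0.08, adjusted p = 0.193 by edgeR) and in the TPM fit with no filter (0.34, adjusted p = 0.0590 by limma). Of 15 epithelial markers, 5 rose and 4 fell (camera adjusted p = 0.379). CD24 was at 0.72 ± 0.05 and DSP at 0.36 ± 0.03, while KRT18 was at -0.15 ± 0.02, a call that was lost on the TPM scale. Of 7 fibroblast and stellate cell markers, POSTN rose (0.70 ± 0.10) and 6 did not pass (camera adjusted p = 0.379). Of 10 leukocyte markers 3 were tested and none passed, among them CD14 at 1.56 ± 0.13 and 1.30 ± 0.164 CPM. None of 8 endothelial and 10 acinar or islet markers passed the count filter.

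Of the 22 lists tested, 13 differed from other genes, 7 upward and 6 downward, and 7 held with an estimated correlation. Median, mean and camera direction differed in sign for the YAP/TAZ, mesenchymal, epithelial, NF-kB and acetylation and lactylation lists. PFKM, CCNE2, CDC6, PSMB9, ATF4, PHGDH, PSAT1, ASNS and SLC7A5 were chosen after their values were seen, as members that moved against their list. Adjusted over the list alone, 1 more gene rose in each of the lysosome, FOXO, proliferation and interferon lists. Adjusted over the list alone, 6 integrin genes rose and 12 fell, 5 heat shock genes rose, 5 epithelial markers fell, 28 nuclear oxidative phosphorylation genes fell and 7 genes of the ATF4 list fell. The counts of the other lists were the same when adjusted over the list alone.

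**Figure D3:**
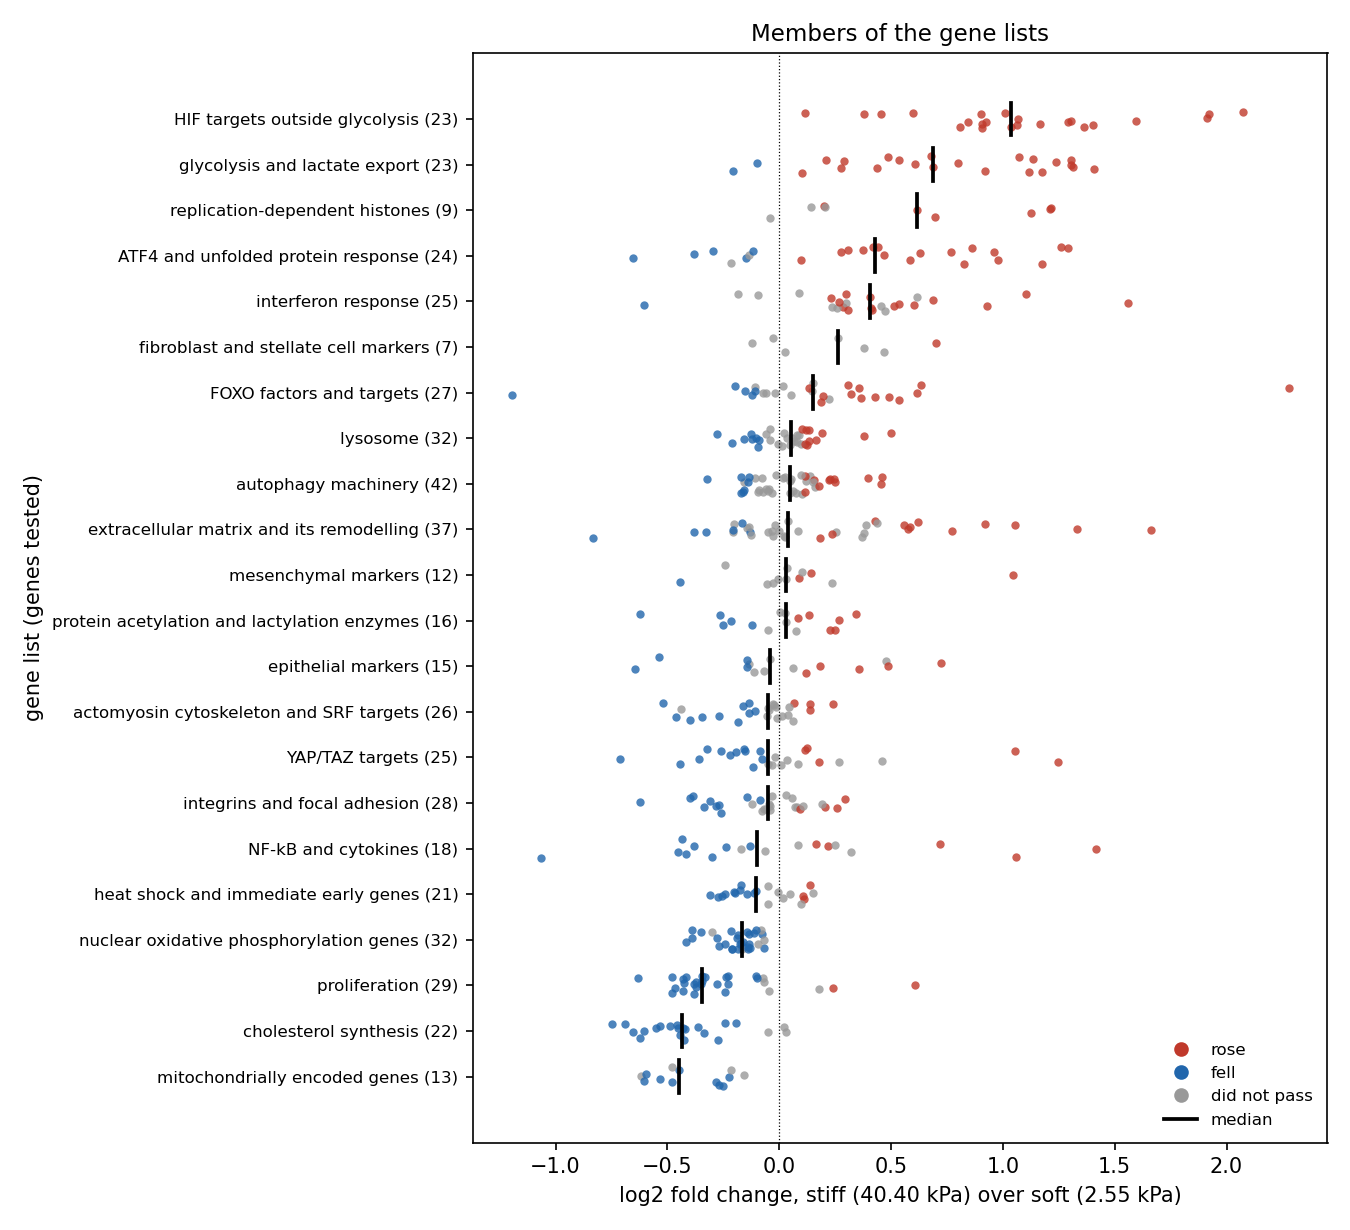
Log2 fold change of stiff over soft (horizontal axis) for each tested gene of the 22 lists, ordered by their median (black bar), with the number of genes tested in parentheses. Red genes rose, blue genes fell and grey genes did not pass. All 23 HIF targets lie above 0, and 19 of 22 cholesterol synthesis genes and 23 of 29 proliferation genes fell.

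Among the pathways that the deposited table assigns to genes, the citrate cycle held 23 fallen genes of 27 where 5.52 were expected (adjusted p = 7.73e-11 by Fisher's exact test). Oxidative phosphorylation held 64 fallen genes of 117 (adjusted p = 3.06e-14), and the proteasome 24 of 38 (adjusted p = 6.11e-07). The GO process of cell division held 131 fallen genes of 312 (adjusted p = 1.29e-14), and mitochondrial translational elongation held 52 of 85 (adjusted p = 5.24e-13). Among risen genes, protein processing in the endoplasmic reticulum held 56 of 135 (adjusted p = 2.68e-07) and canonical glycolysis 14 of 19 (adjusted p = 6.58e-05). The FoxO signaling pathway held 32 risen genes of 102 (adjusted p = 0.0317), which was lost against annotated genes alone (adjusted p = 0.0865). In all, 274 terms passed, 72 for risen and 202 for fallen genes, and 126 passed against annotated genes alone. Fisher's exact test treats genes as independent, so its p-values can be too small for terms whose genes move together. The nuclear and mitochondrially encoded respiratory lists had estimated correlations of 0.167 and 0.669. Both lost their calls once these were allowed for (adjusted p = 0.178 for each by camera). A term that passed need not have moved 1 way. Pathways in cancer passed in both directions, with 93 risen and 93 fallen genes of 346. The median log2 fold change of the FoxO signaling pathway was 0.0013.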

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

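Tests against a 1.2-fold change, with the coefficient of variation set to 10%, with GC and length trends removed, without mitochondrial genes or against annotated genes, and every term count but the main one, were chosen after the results were seen. LDHA kept its direction and call in each setting tried. Of 83 named genes, 70 kept direction and call in each alternative set beforehand. On the TPM scale with pseudocounts of 1, 0.1 and 0.01, 3509, 3505 and 3506 genes changed and 996, 997 and 998 fell. At pseudocounts of 1 and 0.01, 107 and 215 genes changed at least 2-fold. With no TPM filter 2112 changed, 1581 up and 531 down, 97 of them at least 2-fold. Calls shared with the count test numbered 3066 of the 3509. With at least 1 CPM in 3 libraries, 210 genes changed at least 2-fold, since low genes were not tested. Against a 1.2-fold change 1383 passed (802 up, 581 down), and at a coefficient of variation of 10% 2222 passed (1246 up, 976 down). Both settings turn mainly on the size of a change, so their agreement is not separate evidence. The same 17 named genes lost their call in both settings. FOXO3, 1 of them, stayed at 0.19 in both, with adjusted p-values of 1 and 0.318. ANKRD1 ranged from -0.169 to 0.041 with 1 replicate left out, turned positive without stiff replicate 2 (0.041), and turned to 0.018, 0.019 and 0.020 at the 3 TPM pseudocounts (0.018 with no filter). Terms passing numbered 274 at first, 126 against annotated genes, 906 with no count filter, 168, 171 and 174 at the 3 TPM pseudocounts, 419 with no TPM filter, 64 in the 1.2-fold test and 36 at 10%. Lists passing numbered 7 with an estimated correlation and 20 by fry, which does not compare a list with other genes. With an estimated correlation the adjusted p was 0.368 for actomyosin, 0.178 for integrins, matrix and both respiratory lists, and 0.0974 for histones. On the TPM scale actomyosin was at 0.199, 0.219 and 0.221 (0.263 unfiltered), integrins at 0.180, 0.2001 and 0.204 (0.224 unfiltered) and matrix at 0.199, 0.225 and 0.228 (0.0350 unfiltered, where its call was kept). Actomyosin was at 0.131 with GC and length trends removed. Leaving out 1 replicate gave an adjusted p of 0.00587 to 0.0526 for actomyosin and of 0.0213 to 0.0861 for the heat shock list, which was at 0.0113 with no filter. By fry the adjusted p was 0.0241 for autophagy, 0.0252 for lysosome, 0.0150 for YAP/TAZ, 0.0354 for epithelial, 0.00223 for NF-kB, 0.00780 for heat shock and 0.0176 for fibroblast genes. With no TPM filter autophagy was at 0.0136 and lysosome at 0.00525. The cause was not tested for these changes. On the TPM scale, though, the median log2 fold change of all genes tested was 0.068, 0.075 and 0.076 at the 3 pseudocounts, against -0.0019 on counts. At a pseudocount of 1, that upward shift was about the move of UQCRC2 (-0.24 on counts, -0.18 on TPM). KRT18 (-0.15 and -0.055) and LDHB (-0.10 and -0.0063) moved by somewhat more. The shift was too small for the moves of NPC1 (-0.21 and -0.0095) and ERBB3 (-1.19 and -0.42). BECN1 stayed near its value (-0.136 and -0.115), while its standard error rose from 0.044 to 0.072. Leaving out 1 replicate, 5630 to 6041 genes changed. With the replicate number as a block 6243 genes changed, 6183 of them shared, and no named gene or list changed its call. Same-numbered libraries did not deviate together (correlations across genes of -0.0137, -0.0488 and 0.012). These correlations gave no sign of pairing by number, but they cannot exclude it, and libraries with different numbers were not compared in this way. DESeq2 called 4867 genes and left 634 without an adjusted p. At the depth, spread and number of these libraries, 58% of the smallest simulated changes were recovered, and what depth alone limits was not tested.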

Other observations

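The tests of HIF1A, of the proliferation list, of low expression and of genomic DNA by expression level in noncoding genes, and of NRF2 targets and fatty acid synthesis were chosen after the results were seen, and so were the genes and gene lists they rest on. HMOX1 and OSGIN1 stood among the largest rises, and both are known targets of the oxidative stress factor NRF2. Of 20 other NRF2 targets, 13 rose and 3 fell, with a median log2 fold change of 0.27 (p = 0.00298 by camera with an estimated correlation). GCLM rose from 45.5 ± 2.14 to 73.9 ± 0.384 CPM, SLC7A11 from 98.4 ± 1.29 to 147 ± 7.13 CPM and NQO1 from 168 ± 2.07 to 232 ± 3.9 CPM. TALDO1 and PGD were among those that fell. Higher NRF2 activity on the stiff gel is a hypothesis that this test is consistent with.

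FASN was among the largest falls. Of 12 fatty acid synthesis genes, 10 fell and none rose (p = 0.0186 by camera with an estimated correlation). The list was first tested with FASN, which had prompted it, and was then decided on without it. Of the 11 other genes 9 fell, with a median of -0.43. Their p by camera with an estimated correlation was 0.0265. ELOVL6 fell by 0.63, the acetyl-CoA carboxylase gene ACACA by 0.44, and SREBF1, which encodes a regulator of these genes, by 0.50. A lower fatty acid synthesis programme on the stiff gel may therefore extend beyond FASN. TXNIP and its relative ARRDC4 rose together, by 2.28 ± 0.06 and 1.28 ± 0.07.

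HIF targets and glycolysis genes rose in 44 of 46 cases, with a median log2 fold change of 0.92. A bias by GC content and gene length is argued against, since the median was 0.97 with each library's trends removed (0.9743), and 44 genes were still called as risen. A higher HIF1A transcript is argued against too, since HIF1A fell from 245 ± 2.74 to 146 ± 1.31 CPM (log2 fold change -0.75 ± 0.03), but EPAS1, the gene of the other main HIF alpha subunit, rose from 5.21 ± 0.702 to 7.17 ± 0.332 CPM (adjusted p = 0.00339 by edgeR), and its part was not tested. HIF1A-AS3, named as an antisense gene of HIF1A, rose by 1.31 ± 0.06, and without strand its reads may be mixed with those of HIF1A. A denser culture with less oxygen on the stiff gel cannot be told apart from stiffness, because no sample varies density or oxygen at 1 stiffness, and the fall of proliferation genes (median -0.34) could come from either (this test replaced an earlier one on density that could not be made).

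Mitochondrially encoded mRNAs fell by a median of 0.45 on the log2 scale. The rRNA gene MT-RNR1 rose (0.39 ± 0.07), and MT-RNR2 was at -0.096 ± 0.029 (adjusted p = 0.0591 by edgeR). The larger distance of the 2 rRNAs above the mRNA median was 12.62 standard errors, set beforehand as evidence against an even loss of mitochondrial RNA. The rRNA left in a library can depend on how RNA was selected, so this distance cannot decide on a loss of mRNAs. Across the 13 mRNAs the falls varied (heterogeneity Q of 300 on 12 degrees of freedom), which argues against a loss even across them. The called mRNAs also differed, with 2.99 standard errors between the largest and smallest fall, although that picks extremes. Reads moved to nuclear copies do not account for the fall, as the sum of both fell by 0.38 (log2 ratio -0.3812) with no overlap between the groups. Lower mitochondrial expression on the stiff gel stays open as a biological hypothesis that was not tested.

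The 1573 noncoding genes (lincRNA and antisense) had a median log2 fold change of 0.11, against -0.015 for 13129 protein-coding genes, and 231 rose while 71 fell. Whether strand was kept is not given, so antisense genes at any CPM may hold reads of the genes they overlap, which was not tested. Low expression is argued against as the whole cause, since the gap within bins of CPM averaged 0.0799, and GC and length are too, since the gap was 0.130 with the trends removed. Genomic DNA in the stiff libraries, which adds CPM by gene length, is argued against for the 180 noncoding genes at 8 CPM or more. Their median was 0.14 (bootstrap 95% interval 0.0962 to 0.195). It exceeded by 0.133 (0.0857 to 0.184) the 0.0095 that the rise per kb of noncoding genes at 0.5 to 1 CPM would give. The gap to coding genes was -0.0075 under 0.5 CPM and 0.161 at 8 CPM or more. Both intervals are over genes, which all come from the same 6 libraries, so they do not measure the spread between libraries. For genes under 8 CPM genomic DNA stays open. Genes under the count filter took 0.127%, 0.138% and 0.127% of counts in soft and 0.144%, 0.136% and 0.149% in stiff libraries (log2 ratio 0.13). The overlap of the groups had been set beforehand as evidence against genomic DNA, but rests on 1 library in each group. The look at genes of 8 CPM or more and one at nuclear RNAs (MALAT1 fell by 0.45 and NEAT1 rose by 0.31 ± 0.04, which decides nothing) stood for a time in place of the original tests, which were then restored.

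The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. Only 1 of the 10 splits, the real one, gave as many genes, as many 2-fold genes, as many lists or as many terms. The real split gave 6544 changed genes and 324 changed at least 2-fold, and the highest other split gave 0 of each by edgeR, with 181 to 332 genes at an unadjusted p under 0.05. It gave 274 terms against a highest other of 0. It gave 13 lists against a highest other of 9, and the 9 other splits called 5 to 9 lists with camera at the preset correlation. Each of the 9 other splits keeps part of the stiffness difference and puts soft and stiff libraries in the same group. For genes that differ with stiffness, this widens the spread within groups and lowers the number of calls. None of their counts of genes, terms or lists is therefore a count without a change. Their 0 genes and 0 terms are no evidence against a chance split.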
